A study of Homo sapiens with 9 samples.

How the data were processed

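RNA sequencing was done on 9 libraries of HNES1 cells, an embryo-derived human naive pluripotent stem cell line, collected on day 5 of the transition from the naive towards a primed-like state. The 3 groups of 3 libraries are vehicle (DMSO), UNC6852 at 2.5 µM (group PROTAC) and UNC1999 at 1 µM (group UNC). Group and replicate number came from the sample titles, and the series' design text states that the experiment was carried out independently 3 times.

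Per the labels' protocols, total RNA was freed of DNA and made into libraries with a Watchmaker kit and depletion of ribosomal RNA, while the molecule field of the labels reads polyA RNA, so the selection of transcripts is uncertain. Reads were trimmed with Trim Galore 0.6.10 and aligned with HISAT2 2.2.1 to GRCh38, per the submitters' processing notes. The counting tool, its annotation release and its strand setting are not given in the sources used here. The authors deposited 1 table of whole-number read counts per gene, not normalised, with 56312 genes or entries and their GRCh38 coordinates. Of these, 5 carried no gene identifier, and 123 had a symbol found on another entry. For gene types, 35044 of 56307 identifiers matched GENCODE 29 (20539 of the 24187 tested).

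Because the strand setting is unknown, reads of a gene and of a gene overlapping it cannot be told apart, and near-identical copies can trade reads. The counting let overlapping genes share reads: RPPH1 had 1599738 counts over all libraries, and an entry overlapping it on chromosome 14 had 1600215.

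Counts were analysed with edgeR 4.0.16 in R 4.3.3: TMM scaling, the default expression filter by group (24187 genes left), robust quasi-likelihood fits of all 9 libraries by group alone, and a two-sided quasi-likelihood test per comparison with Benjamini-Hochberg adjustment over the genes tested at a false discovery rate of 0.05. Every adjusted p of a gene in the text is from this test. The paired fit is the same model with the replicate number as a block, which was planned as the alternative. The common biological coefficient of variation was 13.2% by group alone and 6.09% in the paired fit, with 6 and 4 residual degrees of freedom. Libraries with the same number deviated together from their group means: the 9 correlations between such libraries were 0.106 to 0.472 (median 0.264), and the 18 between libraries with different numbers were -0.324 to 0.0753 (median -0.160). Deviations within a group cancel out, so positive values for the same number make those for different numbers negative on average. Every pair with the same number was above 0.1, the threshold for treating the numbers as pairs, so paired values stand beside results whose call or count they change. The labels do not state that a number marks the same experiment in each group. A chi-square test found replicates of a group different beyond counting noise in every pair of libraries (chi-square over degrees of freedom 10.7 to 37.4), so none was counted as a copy.

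Choices made before the data were examined were the groups, the tests, 30 gene lists and the rule for named genes. That rule took EED, EZH2, EZH1 and SUZ12, the 10 largest rises and 10 largest falls per comparison with DMSO (6 for PROTAC against UNC) among genes with a symbol, a false discovery rate under 0.05, a group mean of at least 1 CPM and no overlap of the 3 against 3 libraries, and up to 4 members per list. It was applied in the same way to both fits, and other genes named as list members were chosen after their values were seen. The minimum of 1 CPM and the rule of no overlap did not hold for list members. Without overlap all 3 pairs move the same way, so agreement of pairs is fixed in advance for genes named by rank. A call in the paired fit likewise favours genes whose pairs agree. Lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted by Benjamini-Hochberg over 30 lists in 3 comparisons. Of 24 list calls by group alone, 0 held with the correlation estimated from the data, and 2 held in fry, which tests whether a list's genes move one way on balance. The lists covered PRC2, PRC1, histone demethylases and their counterparts, general, naive and primed pluripotency, trophoblast, amnion, endoderm, mesoderm, neural, HOX and other developmental regulators, signalling ligands, cell cycle inhibitors, proliferation, p53, stress, cholesterol, lysosome, hypoxia, the VHL ligase, interferon, germline, imprinted, fibroblast, epithelial to mesenchymal transition, DNA methylation, mitochondrial and histone genes.

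Alternatives were RLE, upper-quartile and library-size scaling, DESeq2 1.42.0, limma-voom, no filter, a filter at 1 CPM in 3 libraries, thinned counts, a fit of the 6 libraries compared, a false discovery rate of 0.01, an absolute log2 fold change of at least 1, and leaving out each library and each replicate number. The same alternatives within the paired fit, and 3 further lists, were added after seeing the data. The p-values of these 3 lists were adjusted together with those of the 30 lists, over 99 tests per fit. This adjustment does not correct for choosing the lists from the same data, so their p-values are descriptive only. With counts simulated from these libraries (UNC against DMSO, 23692 genes), the fit by group alone recovered 0, 31, 35 and 50 of 50 genes changed by 0.3, 0.6, 1 and 2 on the log2 scale with 0 false calls, and the paired fit 24, 45, 49 and 50 with 9 false calls. For PROTAC against DMSO (23726 genes) these were 0, 24, 37 and 49 with 0, and 28, 44, 49 and 50 with 20. Changed genes were drawn among those with a mean of over 50 counts, so recovery at lower counts was not measured. Counts were drawn from the paired fit and hold its replicate effects, so the better recovery of that fit follows from the setting. Each gene was drawn independently around these means, so the simulations lack other correlation between genes of the real libraries. Levels are in CPM, each count relative to the TMM-scaled library total, given as mean ± SD over 3 libraries. Sex-linked marker genes were left out of the text, and results for a few other genes are not reported here.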

Results

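Human naive pluripotent cells of the line HNES1, derived from the inner cell mass of an embryo, were profiled by RNA sequencing after 5 days on the way to the primed state, with Polycomb repressive complex 2 (PRC2) perturbed in different ways. PRC2 deposits the repressive histone mark H3K27me3. UNC6852 is a bifunctional degrader that ties the PRC2 subunit EED to the VHL ubiquitin ligase (group PROTAC), UNC1999 is a catalytic inhibitor of EZH2 and EZH1 (group UNC), and DMSO was the vehicle. Compounds were added a day before the naive medium was withdrawn and were renewed daily. Each group had 3 libraries. Total read counts were 63678362, 84716561 and 42043602 for DMSO 1 to 3, 93642763, 73258536 and 31651742 for PROTAC 1 to 3, and 101081643, 40880924 and 79745392 for UNC 1 to 3. Mitochondrial transcripts took 4.51% ± 0.526 of counts in DMSO, 3.44% ± 0.237 in PROTAC and 3.998% ± 0.667 in UNC (SD, n = 3). The first principal component (26.7% of variance) set the libraries of number 1 apart, with scores of -41.2, -30.2 and -35.7, and PC2 (18.5%) had PROTAC 3 at -58.3 and UNC 2 at 36.1.

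Transcripts of the targeted complex were looked at first. EED, the scaffold subunit that UNC6852 binds, was at 11.7 ± 0.730 CPM in DMSO, 12.4 ± 0.342 in PROTAC and 12.1 ± 0.758 in UNC (SD, n = 3). EZH2, the main catalytic subunit, was at 44.7 ± 3.97, 49.1 ± 3.15 and 53.2 ± 6.28 CPM, its paralog EZH1 at 64.9 ± 7.24, 62.3 ± 11.5 and 63.7 ± 8.80 CPM, and the core subunit SUZ12 at 87.3 ± 3.54, 90.8 ± 5.57 and 94.1 ± 5.79 CPM. No call was made for these genes by group alone, where EZH2 in UNC had a log2 fold change of 0.25 (adjusted p = 0.302). EZH2 rose in UNC in the paired fit, by 0.24 on the log2 scale (SE 0.0631, adjusted p = 0.00746, 3 of 3 pairs). Protein levels and the histone mark were not analysed here. Of 13 PRC2 subunits and cofactors, 2 rose, 1 fell and 10 were not called in the paired fit (2 higher and 1 lower adjusted over the list alone). RBBP4 (0.18) rose and PHF19 (-0.22) fell in UNC. Of 13 PRC2 genes, 1 rose and 12 were not called in the paired fit (1 higher adjusted over the list alone). EPOP, a PRC2-associated protein, rose in PROTAC (log2 fold change 0.29, adjusted p = 0.0473, higher in 3 of 3 pairs).

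UNC1999 against DMSO asks how blocking PRC2 catalysis changes the transcriptome during the transition. ARGFX, a homeobox gene of the early embryo (chromosome 3, 121567949 to 121590622), rose from 3.40 ± 0.785 to 10.8 ± 2.18 CPM (SD, n = 3), a log2 fold change of 1.68 (SE 0.194, adjusted p = 0.00346). HNF4A, a nuclear receptor of liver and visceral endoderm, rose by 1.00. GATA3, a regulator of trophoblast (chromosome 10, 8045378 to 8075198), fell by 1.503, TBXT, the mesoderm factor brachyury, fell by 1.72, and CSMD1, a large transmembrane protein (chromosome 8, 2935353 to 4994972), fell by 2.24. Placental lactogen CSH2 fell by 1.63 and the actin-binding protein TAGLN fell by 1.17.

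**Figure D1:**
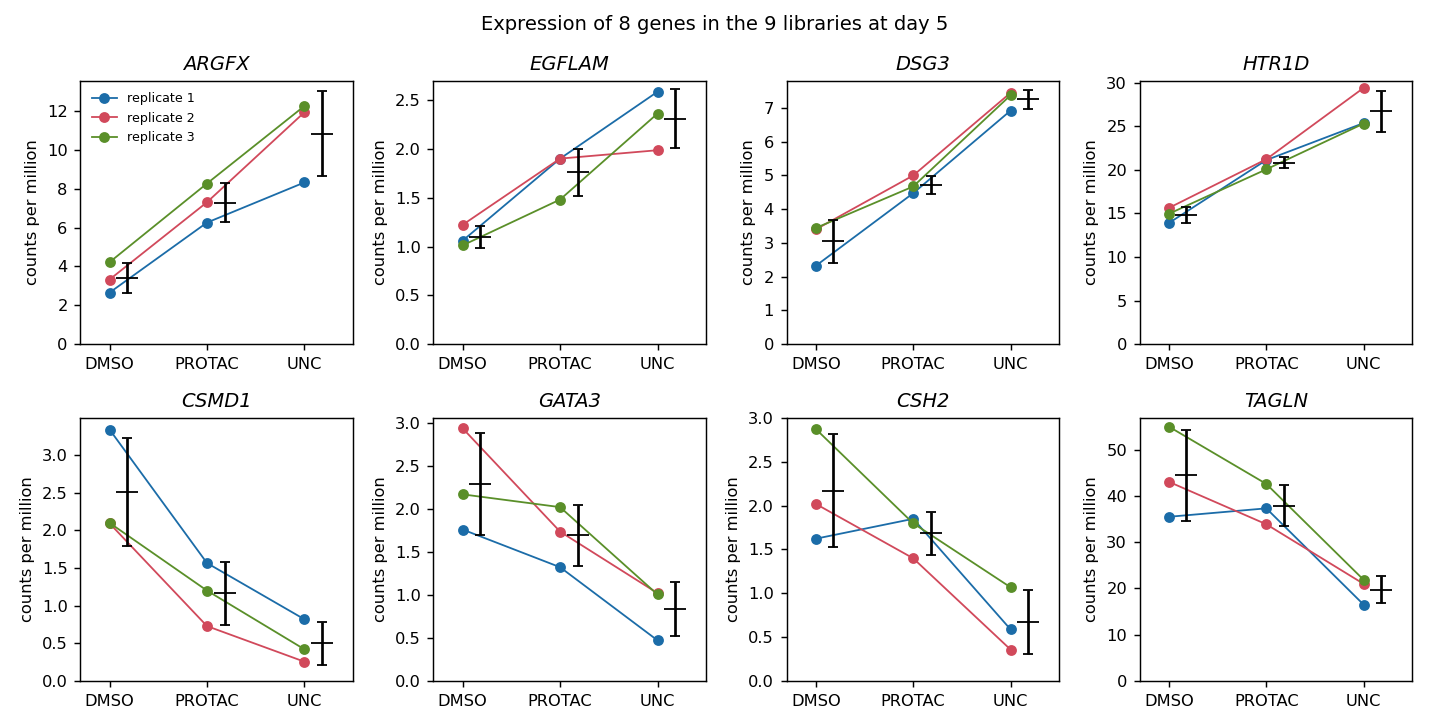
CPM of 8 genes in each library, with lines joining libraries of the same replicate number and black bars giving mean ± SD of each group (n = 3). ARGFX was at 3.40 ± 0.785 CPM in DMSO, 7.28 ± 1.01 in PROTAC and 10.8 ± 2.18 in UNC, and CSMD1 at 2.51 ± 0.717, 1.16 ± 0.420 and 0.497 ± 0.289.

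Other leading rises in UNC were the desmosomal cadherin DSG3 (chromosome 18, 31447741 to 31478702, log2 fold change 1.25, SE 0.158), the matrix protein EGFLAM (1.07), the lysophosphatidic acid receptor LPAR6 (1.01), the ephrin EFNA5 (1.00), the amino acid transporter subunit SLC7A7 (0.98), the serotonin receptor HTR1D (0.85) and the non-coding RNA LINC01500 (0.82). Leading falls were the splicing regulator MBNL2 (-1.65), carbonic anhydrase CA12 (-1.61), the non-coding RNAs LINC03040 (-1.60) and DBET (-1.49), the natriuretic peptide NPPB (-1.49) and CCDC141 (-1.45). Adjusted p of these genes and of HNF4A, GATA3, TBXT, CSMD1 and CSH2 ran from 0.00246 to 0.0496 by edgeR. Each moved the same way in 3 of 3 pairs, which the rule of no overlap fixes for genes named by rank. LPAR6 overlaps RB1, LINC01500 overlaps DACT1, CCDC141 overlaps TTN, and TAGLN, LINC03040 and TBXT overlap other genes. CSH2 has the paralog CSH1, and DBET is multicopy, so their reads may be shared.

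By group alone, 77 genes rose and 97 fell of 24187 tested, with a median absolute log2 fold change of 0.674; 4 of the rises and 39 of the falls were at least 2-fold. Scaled by library size alone the split was 41 and 81. In the paired fit 1703 rose and 1562 fell, 3229 of the 3265 in the same direction in all 3 pairs. Over all genes tested 17.4% had no overlap between groups (chance gives 10%). Of the 174 calls by group alone 172 were also made there, and 2 were not, ANXA1 (-1.14, adjusted p = 0.0762 paired) and NPPB (adjusted p = 0.0544 paired). The paired split was 1165 and 1917 with library size only, and 1335 and 1787 with upper-quartile scaling. Higher and lower counts by group alone were 15 and 35 without DMSO 1, 23 and 21 without DMSO 2, 13 and 25 without DMSO 3, 109 and 168 without UNC 1, 23 and 33 without UNC 2, 13 and 14 without UNC 3, 49 and 151 without all libraries of number 1, 0 and 0 without all libraries of number 2, and 0 and 0 without all libraries of number 3. Paired counts were 982 and 1010 without DMSO 3, 1021 and 961 without UNC 1, 803 and 815 without UNC 2, 1239 and 1009 without UNC 3, 580 and 617 without all libraries of number 2, and 1034 and 928 without all libraries of number 3.

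Many trophoblast genes fell with UNC in the paired fit. Of 38 trophectoderm and trophoblast genes, 2 fell by group alone (1 higher and 13 lower adjusted over the list alone). Paired, 3 rose, 20 fell and 15 were not called (3 higher and 23 lower adjusted over the list alone). The transcription factors GATA3 (-1.52), TFAP2A (-1.44) and GATA2 (-1.08), the syncytins ERVFRD-1 (-1.89) and ERVW-1 (-0.90) and the aminopeptidase ENPEP (-0.95) fell (paired log2 fold changes), while the imprinted retroviral-like gene PEG10 (0.29) rose. Trophoblast genes were lower as a list (camera adjusted p = 2.26e-06, adjusted p = 0.548 with an estimated correlation), 31 of 38 members being negative (median log2 fold change -0.51). Of 21 amnion genes, 1 rose and 3 fell by group alone (3 higher and 6 lower adjusted over the list alone). Paired, 3 rose, 5 fell and 13 were not called (4 higher and 9 lower adjusted over the list alone). WNT6 (-1.40) and TNC (-1.38) fell and BMP4 (0.68) and GADD45G (0.70) rose. Of 112 further homeobox, forkhead, GATA and T-box regulators, 1 rose and 3 fell by group alone (2 higher and 8 lower adjusted over the list alone). Paired, 6 rose, 21 fell and 85 were not called (6 higher and 21 lower adjusted over the list alone). FOXD2 (-2.06), ALX4 (-1.74) and PITX1 (-1.25) fell and ONECUT2 (0.57) rose. FOXD2, ALX4 and PITX1 were under 1 CPM in every library. These developmental regulators were lower as a list (camera adjusted p = 0.000109, adjusted p = 0.0856 with an estimated correlation), 82 of 112 members being negative (median log2 fold change -0.28). Of 15 HOX genes, 1 fell by group alone (1 higher and 2 lower adjusted over the list alone). Paired, 2 rose, 3 fell and 10 were not called (2 higher and 3 lower adjusted over the list alone). HOXD1 (-0.98) fell and HOXB2 (0.67) rose. HOX genes were lower as a list by group alone (camera adjusted p = 0.0374, adjusted p = 0.548 with an estimated correlation), 11 of 15 members being negative (median log2 fold change -0.53), and not in the paired fit (adjusted p = 0.132).

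Germ layer lists held members that went both ways. Of 30 primitive streak and mesoderm genes, 2 fell by group alone (1 higher and 5 lower adjusted over the list alone). Paired, 4 rose, 6 fell and 20 were not called (4 higher and 12 lower adjusted over the list alone). TBXT (-1.79), EOMES (-1.15) and GSC (-1.002) fell and the bHLH factor TWIST1 (0.83) rose. Mesoderm genes were lower as a list (camera adjusted p = 0.0105, adjusted p = 0.386 with an estimated correlation), 22 of 30 members being negative (median log2 fold change -0.31). Of 34 neural ectoderm and neural crest genes, 1 rose by group alone (1 higher adjusted over the list alone). Paired, 4 rose, 7 fell and 23 were not called (4 higher and 7 lower adjusted over the list alone). NKX6-1 (0.65) rose and NEUROG1 (-1.54) and PAX2 (-1.22) fell, the latter 2 under 1 CPM in every library. Neural genes were lower as a list (camera adjusted p = 0.00932, adjusted p = 0.548 with an estimated correlation), 24 of 34 members being negative (median log2 fold change -0.28). Of 23 endoderm genes, 2 rose by group alone (2 higher adjusted over the list alone). Paired, 3 rose, 4 fell and 16 were not called (3 higher and 6 lower adjusted over the list alone). HNF4A (0.98) and LAMB1 (0.36) rose. Of 59 ligands and antagonists of WNT, BMP, TGF-beta, FGF and Hedgehog signalling, 3 rose and 1 fell by group alone (7 higher and 4 lower adjusted over the list alone). Paired, 13 rose, 8 fell and 38 were not called (15 higher and 13 lower adjusted over the list alone). BMP4 (0.68), FGF4 (0.54) and FGF13 (0.47) rose and the BMP antagonist GREM1 (-1.85) fell.

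Pluripotency and chromatin lists held calls in both directions. Of 20 general pluripotency genes, 6 rose, 1 fell and 13 were not called in the paired fit (7 higher and 1 lower adjusted over the list alone). PRDM14 (0.34) and SOX2 (0.27) rose. General pluripotency genes were higher as a list (camera adjusted p = 0.0338, adjusted p = 0.568 with an estimated correlation), 16 of 20 members being positive (median log2 fold change 0.09). Of 39 naive pluripotency genes, 2 rose by group alone (2 higher and 1 lower adjusted over the list alone). Paired, 4 rose, 6 fell and 29 were not called (6 higher and 9 lower adjusted over the list alone). ARGFX (1.68) and FGF4 (0.54) rose and TBX3 (-0.62) and ESRRB (-0.57) fell. Of 40 primed and formative genes, 2 fell by group alone (5 lower adjusted over the list alone). Paired, 7 rose, 13 fell and 20 were not called (9 higher and 14 lower adjusted over the list alone). N-cadherin CDH2 (-0.98), DUSP4 (-0.91) and ZIC2 (-0.54) fell and SPP1 (0.35) rose. CDH2 was under 1 CPM in every library. Of 31 PRC1 subunits, 4 rose, 3 fell and 24 were not called in the paired fit (6 higher and 4 lower adjusted over the list alone). PCGF5 (-0.71) and PHC2 (-0.64) fell. Of 13 histone demethylases and their counterparts, 1 rose, 2 fell and 10 were not called in the paired fit (1 higher and 2 lower adjusted over the list alone). The H3K27 demethylase KDM6B (0.42) rose. Of 13 DNA methylation genes, 1 fell and 12 were not called in the paired fit (1 lower adjusted over the list alone). TET2 (-0.66) fell. Of 37 imprinted genes, 5 rose, 5 fell and 27 were not called in the paired fit (7 higher and 5 lower adjusted over the list alone). H19 (-0.53) and IGF2 (-0.37) fell and the cell cycle inhibitor CDKN1C (0.38) rose.

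Most stress genes rose in UNC in the paired fit. Of 22 genes of the integrated stress and unfolded protein responses, 7 rose by group alone only when adjusted over the list alone. Paired, 15 rose and 7 were not called (17 higher adjusted over the list alone). The pseudokinase TRIB3 (0.54), the cystine transporter SLC7A11 (0.51), the chaperone HSPA5 (0.49) and asparagine synthetase ASNS (0.40) rose. Stress genes were higher as a list (camera adjusted p = 2.26e-06, adjusted p = 0.568 with an estimated correlation), 21 of 22 members being positive (median log2 fold change 0.28). Of 28 hypoxia response genes, 1 rose by group alone (3 higher and 2 lower adjusted over the list alone). Paired, 5 rose, 3 fell and 20 were not called (8 higher and 3 lower adjusted over the list alone). P4HA1 (0.41) and ERO1A (0.33) rose and PFKFB3 (-0.47) fell. Hypoxia genes were higher as a list in the paired fit (camera adjusted p = 0.0430, adjusted p = 0.627 with an estimated correlation), 20 of 28 members being positive (median log2 fold change 0.07), and not by group alone (adjusted p = 0.0559). Of 26 lysosome and autophagy genes, 5 rose, 1 fell and 20 were not called in the paired fit (5 higher and 1 lower adjusted over the list alone). GPNMB (0.58) rose. Lysosome genes were higher as a list in the paired fit (camera adjusted p = 0.0409, adjusted p = 0.627 with an estimated correlation), 18 of 26 members being positive (median log2 fold change 0.08), and not by group alone (adjusted p = 0.116). Of 26 cholesterol genes, 5 rose and 21 were not called in the paired fit (7 higher adjusted over the list alone).

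Fibroblast markers were listed because the naive cells had been kept on mouse feeders. Reads were aligned to the human genome GRCh38, so these counts do not measure feeder content. Of 20 fibroblast markers, 1 rose and 3 fell by group alone (2 higher and 6 lower adjusted over the list alone). Paired, 5 rose, 6 fell and 9 were not called (8 higher and 7 lower adjusted over the list alone). TAGLN (-1.17), COL1A1 (-0.96) and MMP2 (-0.66) fell and COL6A1 (0.56) rose. Of 18 genes of the epithelial to mesenchymal transition, 1 rose and 2 fell by group alone only when adjusted over the list alone. Paired, 5 rose, 3 fell and 10 were not called (7 higher and 3 lower adjusted over the list alone). S100A6 (-0.83) fell. Of 6 cell cycle inhibitors, 2 rose and 4 were not called in the paired fit (2 higher adjusted over the list alone). Of 35 proliferation genes, 4 rose and 31 were not called in the paired fit (4 higher adjusted over the list alone). Of 23 p53 targets, 1 fell by group alone only when adjusted over the list alone. Paired, 2 rose, 1 fell and 20 were not called (3 higher and 1 lower adjusted over the list alone). BTG2 (-0.57) fell. Of 29 interferon response genes, 2 rose, 2 fell and 25 were not called in the paired fit (2 higher and 2 lower adjusted over the list alone). PSMB9 (-0.76) fell. Of 26 germline genes, 1 rose, 2 fell and 23 were not called in the paired fit (1 higher and 2 lower adjusted over the list alone). DMRT1 (-0.81) fell. Of 7 VHL ligase genes, 1 rose by group alone only when adjusted over the list alone. Paired, 1 rose and 6 were not called (1 higher adjusted over the list alone). CUL2 (0.21) rose. Of 13 replication-dependent histone genes, 2 rose and 11 were not called in the paired fit (2 higher adjusted over the list alone). Of 13 mitochondrially encoded mRNAs, 13 were not called in the paired fit (no member passed adjusted over the list alone). Signs differed between the median, the mean and the camera direction by group alone for fibroblast markers (0.04, -0.06, down), epithelial to mesenchymal transition (0.08, -0.03, up), imprinted genes (0.04, -0.03, up), DNA methylation (0.01, -0.05, down) and cell cycle inhibitors (-0.01, 0.03, up), none of them called.

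UNC6852 against DMSO asks the same of EED degradation. ARGFX rose in the paired fit from 3.40 ± 0.785 to 7.28 ± 1.01 CPM (SD, n = 3), a log2 fold change of 1.12 (SE 0.108, adjusted p = 5.01e-08), and the pancreatic and neural homeobox gene NKX6-1 rose by 0.74. CSMD1 fell by 1.17, and the naive pluripotency factors TBX3 and ESRRB fell by 0.60 and 0.50. Of 26 cholesterol genes 16 rose, the sterol oxidase MSMO1 by 0.47. None of the genes named here was called by group alone.

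Further paired rises were guanine deaminase GDA (0.77), the metalloproteinase MMP16 (0.75), EGFLAM (0.69), the homeobox factor ONECUT2 (0.68), TMEM45A (0.67), DSG3 (0.65) and PLXDC2 (0.65). Falls were the lectin receptor CLEC9A (-1.12), the non-coding RNAs CARMN (-1.10), LINC00896 (-1.02), CYP4A22-AS1 (-0.89), PHKA2-AS1 (-0.83) and SNHG20 (-0.77), the pseudogene BMS1P14 (-0.89), LRRN2 (-1.05) and the transporter ABCC2 (-0.82). Adjusted p of these and the genes above ran from 5.01e-08 to 0.0405 in the paired fit. Each had the same direction in 3 of 3 pairs, again fixed by the rule of no overlap for genes named by rank. PHKA2-AS1, SNHG20, CYP4A22-AS1, LINC00896, BMS1P14 and LRRN2 overlap other genes, so their reads may be shared.

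By group alone edgeR called 0 genes, with 1200 at an unadjusted p under 0.05 where 1209 would be expected by chance and a smallest adjusted p of 0.328. On the same design DESeq2 called 13 higher and 10 lower, limma-voom 0, and edgeR without a filter 35 higher and 37 lower. In the paired fit 486 genes rose and 238 fell, all 724 in the same direction in 3 of 3 pairs. Groups did not overlap in 11.5% of all genes tested (chance gives 10%). The changes were small, with a median absolute log2 fold change of 0.287 and 3 rises and 15 falls of at least 2-fold. The split of 486 and 238 became 273 and 265 with library size only and 308 and 260 with upper-quartile scaling. Higher and lower paired counts were 279 and 164 without DMSO 2, 154 and 81 without DMSO 3, 248 and 122 without PROTAC 1, 327 and 146 without PROTAC 2, 201 and 117 without PROTAC 3, 91 and 56 without all libraries of number 2, and 99 and 66 without all libraries of number 3.

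Most cholesterol genes rose with PROTAC in the paired fit. Of 26 cholesterol synthesis and uptake genes, 16 rose and 10 were not called in the paired fit (21 higher adjusted over the list alone). MSMO1 (0.47), HMGCS1 (0.37), INSIG1 (0.37) and STARD4 (0.37) rose. Cholesterol genes were higher as a list (camera adjusted p = 4.64e-06, adjusted p = 0.582 with an estimated correlation), 26 of 26 members being positive (median log2 fold change 0.24). Of 22 integrated stress and unfolded protein response genes, 9 rose and 13 were not called in the paired fit (17 higher adjusted over the list alone). DDIT4 (0.29), HSPA5 (0.27) and ASNS (0.23) rose. Stress response genes were higher as a list (camera adjusted p = 1.50e-05, adjusted p = 0.568 with an estimated correlation), 21 of 22 members being positive (median log2 fold change 0.19). Of 28 hypoxia genes, 1 rose by group alone only when adjusted over the list alone. Paired, 7 rose and 21 were not called (9 higher and 1 lower adjusted over the list alone). The collagen hydroxylase P4HA1 (0.37), ERO1A (0.28) and LDHA (0.26) rose. Hypoxia response genes were higher as a list (camera adjusted p = 0.000273, adjusted p = 0.568 with an estimated correlation), 23 of 28 members being positive (median log2 fold change 0.12). Of 23 p53 target genes, 4 rose and 19 were not called in the paired fit (7 higher adjusted over the list alone). CDKN1A (0.27) and SESN1 (0.19) rose. p53 targets were higher as a list (camera adjusted p = 0.00350, adjusted p = 0.548 with an estimated correlation), 18 of 23 members being positive (median log2 fold change 0.09). Of 13 mitochondrial mRNAs, 13 fell by group alone only when adjusted over the list alone. Paired, 13 were not called (5 lower adjusted over the list alone). Mitochondrial mRNAs were lower as a list (camera adjusted p = 2.18e-09, adjusted p = 0.548 with an estimated correlation), 13 of 13 members being negative (median log2 fold change -0.40). The mitochondrial share of counts was lower in PROTAC than in DMSO in 3 of 3 pairs, beside the rises of the lists above.

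Among developmental genes with PROTAC, NKX6-1 rose and the placental syncytins fell. Of 34 neural genes, 1 rose by group alone only when adjusted over the list alone. Paired, 4 rose and 30 were not called (5 higher and 2 lower adjusted over the list alone). NKX6-1 (0.74) rose. Of 112 homeobox, forkhead, GATA and T-box regulators, 1 rose by group alone only when adjusted over the list alone. Paired, 6 rose, 3 fell and 103 were not called (9 higher and 9 lower adjusted over the list alone). ONECUT2 (0.68) and FOXC2 (0.53) rose and TBX3 (-0.60) and NKX2-5 (-0.53) fell. Of 38 trophoblast genes, 1 rose, 3 fell and 34 were not called in the paired fit (1 higher and 7 lower adjusted over the list alone). ERVFRD-1 (-1.05) and ERVW-1 (-0.63) fell and PEG10 (0.47) rose. Trophectoderm genes were lower as a list in the paired fit (camera adjusted p = 0.0152, adjusted p = 0.551 with an estimated correlation), 29 of 38 members being negative (median log2 fold change -0.16), and not by group alone (adjusted p = 0.0579). Of 39 genes of naive pluripotency, 2 rose by group alone only when adjusted over the list alone. Paired, 4 rose, 2 fell and 33 were not called (6 higher and 2 lower adjusted over the list alone). ARGFX (1.12), KLF17 (0.29) and FGF4 (0.28) rose. Of 40 genes of primed and formative pluripotency, 1 fell by group alone only when adjusted over the list alone. Paired, 5 rose, 3 fell and 32 were not called (8 higher and 5 lower adjusted over the list alone). SPP1 (0.47) and LRRN1 (0.44) rose and ZIC5 (-0.56) and ZIC2 (-0.39) fell. Of 20 general pluripotency factors, 1 rose and 19 were not called in the paired fit (7 higher adjusted over the list alone). SOX2 (0.25) rose. Pluripotency factors were higher as a list (camera adjusted p = 0.00932, adjusted p = 0.548 with an estimated correlation), 16 of 20 members being positive (median log2 fold change 0.06). Of 21 amnion markers, 1 rose by group alone only when adjusted over the list alone. Paired, 2 rose and 19 were not called (2 higher adjusted over the list alone). GADD45G (0.58) and BMP4 (0.55) rose. Of 30 mesoderm genes, 2 rose, 1 fell and 27 were not called in the paired fit (2 higher and 5 lower adjusted over the list alone). TWIST1 (0.61) rose. Of 59 signalling ligands and antagonists, 3 rose by group alone only when adjusted over the list alone. Paired, 6 rose, 1 fell and 52 were not called (10 higher and 1 lower adjusted over the list alone). BMP4 (0.55) rose and FGF18 (-0.60) fell.

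The remaining lists held few or no paired calls. Of 18 epithelial to mesenchymal transition genes, 2 rose and 16 were not called in the paired fit (5 higher adjusted over the list alone). TWIST1 (0.61) and CLDN6 (0.17) rose. Epithelial to mesenchymal transition genes were higher as a list (camera adjusted p = 0.0105, adjusted p = 0.548 with an estimated correlation), 14 of 18 members being positive (median log2 fold change 0.12). This list mixes epithelial and mesenchymal genes, so its direction does not show a move along the transition. Of 37 imprinted loci, 2 rose and 35 were not called in the paired fit (2 higher adjusted over the list alone). PEG10 (0.47) and CDKN1C (0.41) rose. Imprinted genes were higher as a list in the paired fit (camera adjusted p = 0.0409, adjusted p = 0.378 with an estimated correlation), 24 of 37 members being positive (median log2 fold change 0.06), and not by group alone (adjusted p = 0.0579). Of 26 lysosomal genes, 26 were not called in the paired fit (no member passed adjusted over the list alone). Lysosomal genes were higher as a list in the paired fit (camera adjusted p = 0.0409, adjusted p = 0.627 with an estimated correlation), 21 of 26 members being positive (median log2 fold change 0.06), and not by group alone (adjusted p = 0.156). Of 31 PRC1 genes, 3 rose and 28 were not called in the paired fit (4 higher adjusted over the list alone). SCML1 (0.40) rose. Of 20 fibroblast genes, 1 rose and 1 fell by group alone only when adjusted over the list alone. Paired, 1 rose, 2 fell and 17 were not called (3 higher and 3 lower adjusted over the list alone). COL1A1 (-0.34) and MMP2 (-0.34) fell and COL6A1 (0.36) rose. Of 6 inhibitors of the cell cycle, 2 rose and 4 were not called in the paired fit (3 higher adjusted over the list alone). CDKN1A (0.27) and CDKN1C (0.41) rose. Of 23 endoderm markers, 2 rose and 21 were not called in the paired fit (2 higher and 2 lower adjusted over the list alone). HNF4A (0.44) and LAMB1 (0.24) rose. Of 15 HOX family genes, 1 rose and 14 were not called in the paired fit (1 higher and 1 lower adjusted over the list alone). HOXB2 (0.28) rose. Of 29 interferon genes, 1 rose and 28 were not called in the paired fit (2 higher and 2 lower adjusted over the list alone). HLA-B (0.24) rose. Of 26 germline markers, 1 fell and 25 were not called in the paired fit (1 lower adjusted over the list alone). SYCP2 (-0.61) fell. Of 7 genes of the VHL ligase, 7 were not called in the paired fit (1 higher adjusted over the list alone). Of 35 genes of proliferation, 35 were not called in the paired fit (no member passed adjusted over the list alone). Of 13 genes of DNA methylation, 13 were not called in the paired fit (no member passed adjusted over the list alone). Of 13 histone genes, 13 were not called in the paired fit (no member passed adjusted over the list alone). Of 13 histone demethylase genes, 13 were not called in the paired fit (no member passed adjusted over the list alone). Median, mean and camera direction by group alone differed in sign for amnion (0.06, -0.00269, up), endoderm (0.03, -0.22, up), germline (-0.03, 0.00270, up) and DNA methylation genes (0.00946, -0.03, down), none of them called.

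**Figure D2:**
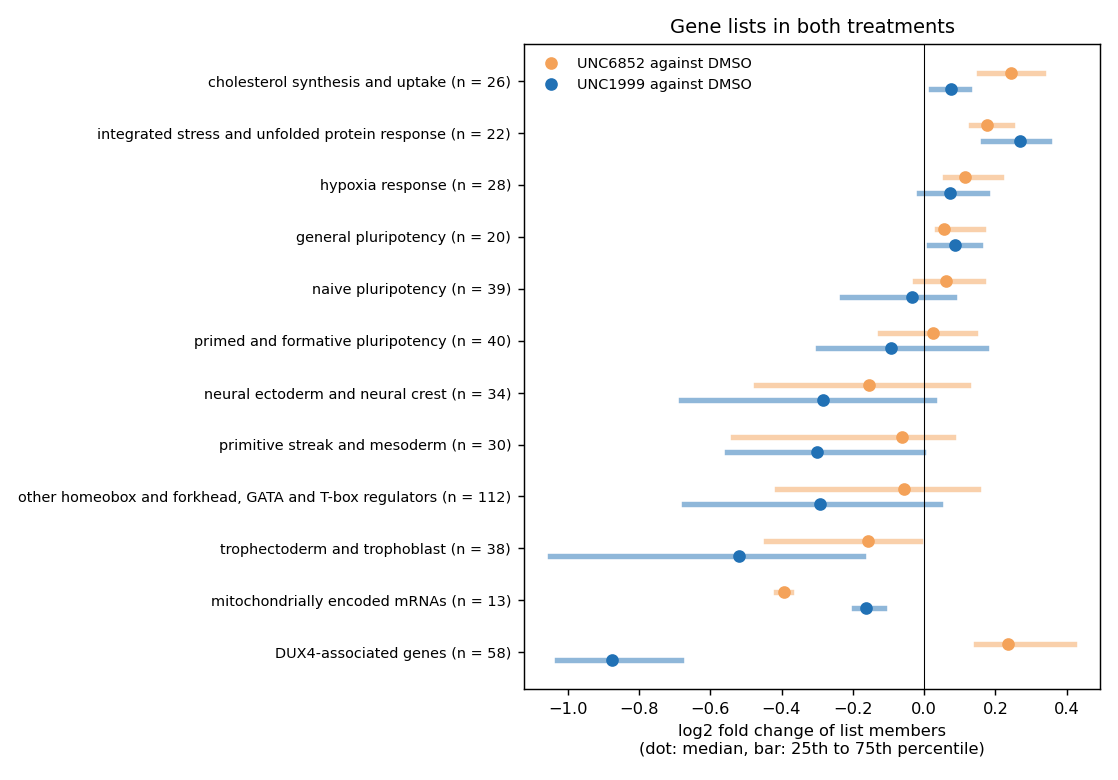
Median (dot) and 25th to 75th percentile (bar) of the paired log2 fold change of the members of 12 gene lists, with UNC6852 in orange and UNC1999 in blue. The cholesterol list has a median of 0.24 with UNC6852 and 0.07 with UNC1999, the trophoblast list -0.16 and -0.52, and the list of DUX4-associated genes was written after values had been seen.

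Fold changes of both treatments were compared gene by gene. Paired, 371 genes rose with both compounds, among them ARGFX, DSG3, EGFLAM, BMP4, TWIST1 and SOX2, and 171 fell with both, among them CSMD1, ERVFRD-1, TBX3, ESRRB, ZIC2 and COL1A1. For ARGFX the paired log2 fold change was 1.12 with PROTAC and 1.68 with UNC, and for CSMD1 -1.17 and -2.33. The 542 shared calls compare with 34.2 and 15.4 for independent lists of these sizes, with at most 3 in 20 simulations of unchanged groups against the same controls, and with 5 calls in opposite directions. Genes were simulated independently, so shared calls in real unchanged libraries may vary more. Relabelled real libraries, which can keep treatment differences, gave up to 232. By group alone the real number of shared calls was 0 by edgeR, since no gene was called with PROTAC (1200 at an unadjusted p under 0.05), and 20 by DESeq2 and 0 by limma-voom. Paired shared calls numbered 339 without DMSO 2, 183 without DMSO 3, 298 without PROTAC 1, 347 without PROTAC 2, 263 without PROTAC 3, 312 without UNC 2, 98 without all libraries of number 2, and 133 without all libraries of number 3.

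Across 24187 genes, which are not independent replicates, the covariance of the fold changes was 0.0594 by group alone against a simulated 0.0301 with unchanged groups (highest 0.0313), a difference of 0.0293, and the correlation was 0.542 against 0.503. The simulated range is too narrow where real genes move together, since genes were simulated independently. The covariance was 0.104 without DMSO 1, 0.110 without DMSO 2, and 0.0923 without all libraries of number 2. Genes of low counts add to it. Between libraries that share no control it had a mean of 0.0263 over all genes and 0.0158 over genes above 2 CPM. The 3 control libraries cannot be split into parts that each keep replicates, so part of the excess of shared calls may come from the shared controls.

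**Figure D3:**
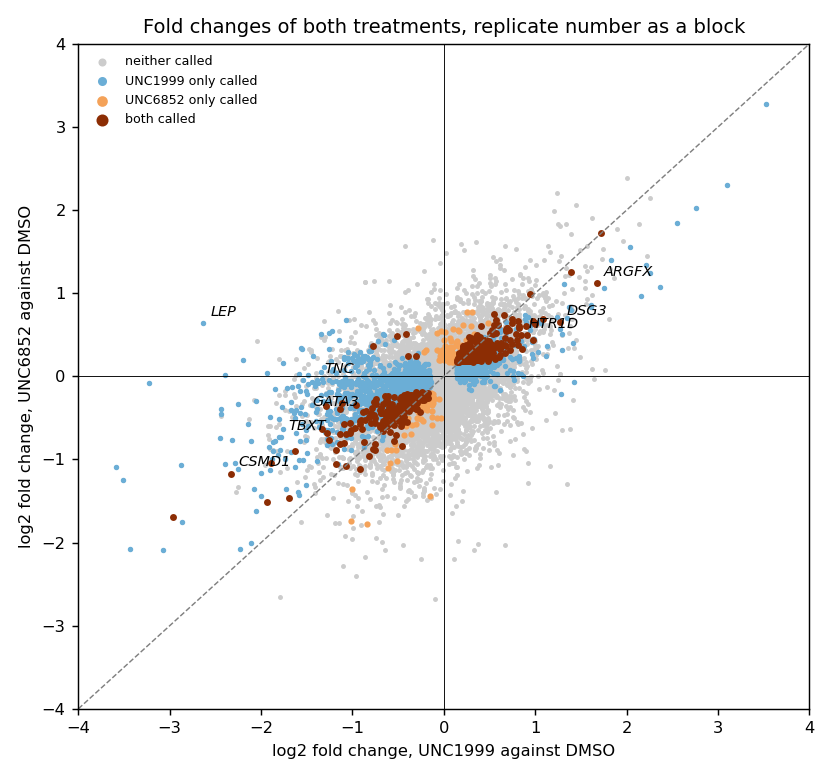
Paired log2 fold change with UNC6852 (vertical axis) against UNC1999 (horizontal axis) for each gene tested, coloured by which comparison called it, with a dashed line of equal change. Of the genes called in both comparisons 542 lie in the quadrants of equal sign and 5 in the others.

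Setting the compounds against each other, at 2.5 µM for UNC6852 and 1 µM for UNC1999, so at unequal doses, tests where their effects differed. By group alone IMPDH1, an enzyme of guanine nucleotide synthesis, was higher with PROTAC (22.4 ± 1.51 CPM) than with UNC (12.6 ± 0.939 CPM), with DMSO at 20.4 ± 1.37 (SD, n = 3). The protease subunit CAPN2 was at 21.3 ± 1.41 CPM with PROTAC and 13.0 ± 0.786 with UNC. Log2 differences were 0.83 (SE 0.0955, adjusted p = 0.0218) and 0.72 (SE 0.0939, adjusted p = 0.0477), with PROTAC higher in 3 of 3 pairs. These 2 genes were the whole of the calls, with none lower by edgeR, 1137 genes at an unadjusted p under 0.05, 110 higher and 19 lower by DESeq2, and 1 and 0 by limma-voom. Higher and lower counts were 0 and 0 without PROTAC 1, 0 and 0 without PROTAC 3, 6 and 0 without UNC 1, 1 and 0 without UNC 2, 0 and 0 without UNC 3, 33 and 2 without all libraries of number 1, 0 and 0 without all libraries of number 2, and 0 and 0 without all libraries of number 3.

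With pairing, 524 genes were higher with PROTAC and 179 lower, 697 of 703 in the same direction in 3 of 3 pairs. The compounds did not overlap in 9.09% of all genes tested (chance gives 10%). Higher with PROTAC were leptin LEP (3.28), TRIM51 (1.88), the BMP antagonist GREM1 (1.69), FRG2C (1.67), TRIM48 (1.48), DSCR10 (1.42), the trophoblast and surface ectoderm factor TFAP2A (1.38), tenascin TNC (1.34), GATA3 (1.07) and TBXT (1.05). Lower were the catenin CTNNA3 (-0.88), the protocadherin PCDH12 (-0.77), the urea cycle enzyme CPS1 (-0.76), UNC93A (-0.75), the sialyltransferase ST6GALNAC1 (-0.75), the histone H2AC19 (-0.72) and ARGFX (-0.55). Adjusted p ran from 1.82e-08 to 0.0474 with 3 of 3 pairs in each, which the rule of no overlap fixes for genes named by rank. TRIM51, TRIM48 and FRG2C are multicopy genes that can share reads. LEP, DSCR10, ST6GALNAC1 and TBXT overlap other genes. LEP was at 0.0289, 0.204 and 0.102 CPM in UNC 1 to 3. There 3 counts correspond to 0.0297, 0.0734 and 0.0376 CPM of the total before TMM scaling, so the 2 scales differ slightly. For BMP4 the paired difference between the compounds was -0.14 (SE 0.0894, adjusted p = 0.579), not called. Paired counts were 347 and 70 without PROTAC 2, 371 and 98 without PROTAC 3, 317 and 81 without UNC 1, 357 and 83 without UNC 2, 282 and 71 without UNC 3, 274 and 45 without all libraries of number 2, and 261 and 71 without all libraries of number 3.

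Trophoblast, developmental, cholesterol, amnion and primed genes were higher with PROTAC than with UNC as lists, none of them with an estimated correlation. Of 38 trophoblast list genes, 9 were higher and 29 were not called in the paired fit (16 higher and 2 lower adjusted over the list alone), with TFAP2A (1.38), GATA3 (1.07) and GATA2 (1.03) among them. Trophoblast list genes were higher as a list (camera adjusted p = 4.53e-06, adjusted p = 0.548 with an estimated correlation), 31 of 38 members being positive (median log2 fold change 0.31). Of 112 developmental regulators, 10 were higher and 102 were not called in the paired fit (13 higher adjusted over the list alone), with PITX1 (1.06) and FOXD1 (0.93) among them. Developmental regulators were higher as a list (camera adjusted p = 0.000273, adjusted p = 0.0856 with an estimated correlation), 78 of 112 members being positive (median log2 fold change 0.26). Of 26 cholesterol pathway genes, 7 were higher and 19 were not called in the paired fit (21 higher adjusted over the list alone), with LSS (0.27) among them. Cholesterol pathway genes were higher as a list (camera adjusted p = 0.00128, adjusted p = 0.742 with an estimated correlation), 24 of 26 members being positive (median log2 fold change 0.16). Of 21 amnion list genes, 5 were higher by group alone only when adjusted over the list alone. Paired, 4 were higher and 17 were not called (7 higher adjusted over the list alone), with TNC (1.34) and WNT6 (0.97) among them. Amnion genes were higher as a list (camera adjusted p = 0.0105, adjusted p = 0.548 with an estimated correlation), 13 of 21 members being positive (median log2 fold change 0.21). Of 40 primed list genes, 8 were higher, 1 was lower and 31 were not called in the paired fit (11 higher and 3 lower adjusted over the list alone), with DUSP4 (0.62) and SOX11 (0.55) among them. Primed genes were higher as a list (camera adjusted p = 0.00774, adjusted p = 0.587 with an estimated correlation), 30 of 40 members being positive (median log2 fold change 0.10).

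Further lists were called between the compounds. Of 59 signalling genes, 3 were higher and 1 was lower by group alone only when adjusted over the list alone. Paired, 4 were higher, 1 was lower and 54 were not called (9 higher and 4 lower adjusted over the list alone). Signalling genes were higher as a list (camera adjusted p = 0.00932, adjusted p = 0.548 with an estimated correlation), 38 of 59 members being positive (median log2 fold change 0.16). Of 34 neural list genes, 34 were not called in the paired fit (no member passed adjusted over the list alone). Neural list genes were higher as a list (camera adjusted p = 0.0424, adjusted p = 0.548 with an estimated correlation), 25 of 34 members being positive (median log2 fold change 0.14). Of 15 HOX list genes, 1 was lower and 14 were not called in the paired fit (4 higher and 1 lower adjusted over the list alone). HOX list genes were higher as a list by group alone (camera adjusted p = 0.0273, adjusted p = 0.548 with an estimated correlation), 11 of 15 members being positive (median log2 fold change 0.14), and not in the paired fit (adjusted p = 0.128). Of 30 mesoderm list genes, 5 were higher and 25 were not called in the paired fit (5 higher and 1 lower adjusted over the list alone). Mesoderm list genes were higher as a list in the paired fit (camera adjusted p = 0.0409, adjusted p = 0.378 with an estimated correlation), 19 of 30 members being positive (median log2 fold change 0.18), and not by group alone (adjusted p = 0.0559). Of 23 p53 list genes, 1 was higher by group alone only when adjusted over the list alone. Paired, 1 was higher and 22 were not called (2 higher adjusted over the list alone). p53 list genes were higher as a list (camera adjusted p = 0.0338, adjusted p = 0.568 with an estimated correlation), 18 of 23 members being positive (median log2 fold change 0.09). Of 22 stress list genes, 2 were lower and 20 were not called in the paired fit (4 lower adjusted over the list alone). Stress list genes were lower as a list in the paired fit (camera adjusted p = 0.0152, adjusted p = 0.670 with an estimated correlation), 19 of 22 members being negative (median log2 fold change -0.07), and not by group alone (adjusted p = 0.0680). Mitochondrially encoded mRNAs were lower as a list (camera adjusted p = 7.94e-05, adjusted p = 0.568 with an estimated correlation), 13 of 13 members being negative (median log2 fold change -0.24).

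The fibroblast and naive lists were not called between the compounds (camera adjusted p = 0.0824 and 0.136 by group alone, 0.0589 and 0.176 in the paired fit), and single members were in the paired fit. Of 20 fibroblast list genes, 6 were higher and 1 was lower by group alone only when adjusted over the list alone. Paired, 6 were higher, 1 was lower and 13 were not called (8 higher and 1 lower adjusted over the list alone), with TAGLN (0.96) and COL1A1 (0.62) higher with PROTAC. Of 39 naive list genes, 1 was higher and 1 was lower by group alone only when adjusted over the list alone. Paired, 6 were higher, 3 were lower and 30 were not called (7 higher and 4 lower adjusted over the list alone), with ARGFX (-0.55) lower with PROTAC. Median, mean and camera direction by group alone differed in sign between the compounds for cell cycle inhibitors (-0.00676, 0.02, up), VHL ligase genes (-0.000174, 0.02, up) and interferon genes (-0.00872, 0.04, up), none of them called.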

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

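All tests of explanations here and the list of DUX4-associated genes were chosen after the results had been seen, and 4 results stood out because the compounds differed from each other in a direct test. The p-values of the DUX4-associated list are therefore descriptive only. IMPDH1 (log2 difference 0.832) and CAPN2 (0.715) were higher with PROTAC than with UNC by group alone, in 3 of 3 pairs. The call of IMPDH1 ended without PROTAC 1, PROTAC 3 or UNC 3 (adjusted p = 0.0852, 0.280 and 0.302), and that of CAPN2 without any 1 of the PROTAC or UNC libraries (adjusted p = 0.0502 to 0.321 over these 6 fits, with log2 differences of 0.66 to 0.76). In the paired fit 703 genes differed between the compounds. Of 10 splits of the 6 libraries the real one gave 2 genes and the highest of the others 0, with 1 split as large, and of 4 splits that part every pair the real one gave 703 and the highest other 0, with 1 as large. Both sets of splits are too few for a share under 0.05.

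The last is a group of genes switched on by DUX4, a transcription factor of genome activation in the early embryo: 44 of 58 were higher with PROTAC than with UNC in the paired fit and 14 were not called (camera adjusted p = 5.41e-47, and adjusted p = 0.219 with an estimated correlation, 58 members positive and 0 negative). By group alone edgeR called 0 of them (47 higher at an unadjusted p under 0.05), DESeq2 16 and limma-voom 0 (camera adjusted p = 8.06e-42, adjusted p = 0.469 with an estimated correlation), so the list's call is lost with an estimated correlation in both fits. Against DMSO in the paired fit 39 fell with UNC, such as H3Y1 (-1.01), TRIM43 (-0.99), KDM4E (-0.95) and SLC34A2 (-0.95), and 2 rose with PROTAC, where 51 of 58 were positive (median 0.23, camera adjusted p = 1.01e-06, adjusted p = 0.482 with an estimated correlation). The rise with PROTAC was largest in pair 1. There the list's mean log2 CPM went from 1.20 to 1.69, against 0.707 to 0.815 in pair 2 and 0.836 to 0.991 in pair 3. By group alone 1 fell with UNC by edgeR (32 at an unadjusted p under 0.05), 10 by DESeq2 and 0 by limma-voom, and 0 rose with PROTAC by each of these tools (1 at an unadjusted p under 0.05 by edgeR). The median difference of 1.13 became 1.01 at the lowest and 1.24 at the highest when 1 library was left out, which argues against a single library as the cause. Reads traded between near-identical copies are argued against by the members with no such copy, with a median of 1.01 over 5 genes, of which 4 were called. Members with such copies can share reads, so the counts over the 58 members are not counts of independent genes. A lower share of residual naive cells with UNC would lower genes made only by those cells. The naive list had a median difference of 0.0598 (SD 0.230), with 2 genes in both lists. Whether its members are made only by residual naive cells was not tested, so this value cannot decide on that explanation. A smaller subset of cells with DUX4 activity that differs between the compounds, by their target or by their dose, may underlie the pattern and stays untested.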

How the results depend on the processing

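No call of a named gene or list reversed under an alternative run, where camera with an estimated correlation could not change a list's direction. The balance of higher and lower counts was not part of that check. For UNC against DMSO in the paired fit it turned over with library-size and upper-quartile scaling. By group alone, 911 alternative values of 48 results for named genes gave 603 with the call kept, 307 with it lost and 1 with it gained, and in the paired fit 4840 values of 256 results gave 3753, 1086 and 1. Of 24 list calls, library-size scaling kept 21 (not general pluripotency and HOX genes in UNC, nor neural genes between the compounds) and the paired fit 22 with 7 gained, and for the 30 lists the block changed no other call than those given here and in the comparisons. Its effect on the lists added later stands beside their counts. The smallest libraries, PROTAC 3 (31651742 counts) and UNC 2 (40880924), limit the precision of genes with low counts, and thinning all libraries to the depth of the smallest kept the counts of calls within 1.5 times except where given. The cause of the changed counts was not tested, except that stricter thresholds call fewer genes by construction. Leaving out libraries lowered some counts and raised others. In the simulation of PROTAC against DMSO the paired fit made 20 false calls and the fit by group alone 0, so paired counts can hold more false calls than the threshold implies.

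Counts of calls by group alone (0 for PROTAC against DMSO, 77 higher and 97 lower for UNC against DMSO, 2 higher for PROTAC against UNC) that moved by over 1.5 times were as follows. The replicate block gave 486 higher and 238 lower for PROTAC against DMSO, 1703 higher and 1562 lower for UNC against DMSO, 524 higher and 179 lower for PROTAC against UNC, and 542 shared by both treatments. DESeq2 gave 13 higher and 10 lower for PROTAC against DMSO, 404 higher and 397 lower for UNC against DMSO, 110 higher and 19 lower for PROTAC against UNC, and 20 shared by both treatments. No filter gave 35 higher and 37 lower for PROTAC against DMSO, 356 higher and 478 lower for UNC against DMSO, 208 higher and 38 lower for PROTAC against UNC, and 45 shared by both treatments. Library-size scaling gave 41 higher for UNC against DMSO. RLE scaling gave 1 higher for PROTAC against UNC. Limma-voom gave 1 higher for PROTAC against UNC. The stricter filter gave 1 higher for PROTAC against UNC. Thinned counts gave 1 higher for PROTAC against UNC. A fit of the 6 libraries compared gave 22 higher and 51 lower for UNC against DMSO, and 0 higher for PROTAC against UNC. A false discovery rate of 0.01 left 15 higher and 20 lower for UNC against DMSO, and 0 higher for PROTAC against UNC. An absolute log2 fold change of at least 1 left 4 higher and 39 lower for UNC against DMSO, and 0 higher for PROTAC against UNC. Without a filter the covariance of fold changes was 0.552. With edgeR, leaving out a library or a replicate number gave 0 to 0 higher and 0 to 0 lower for PROTAC against DMSO, 0 to 109 higher and 0 to 168 lower for UNC against DMSO, 0 to 33 higher and 0 to 2 lower for PROTAC against UNC, 0 to 0 shared and a covariance of 0.0641 to 0.110.

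For the paired fit, whose alternatives were chosen after seeing the data except the removal of the block, the fit with no replicate block gave 0 higher and 0 lower for PROTAC against DMSO, 77 higher and 97 lower for UNC against DMSO, 2 higher and 0 lower for PROTAC against UNC, and 0 shared by both treatments. In this fit library-size scaling gave 273 higher for PROTAC against DMSO. In this fit upper-quartile scaling gave 308 higher for PROTAC against DMSO. Paired limma-voom gave 382 lower for PROTAC against DMSO, and 322 lower for PROTAC against UNC. Here a fit of the 6 libraries compared gave 293 higher and 142 lower for PROTAC against DMSO, and 355 shared by both treatments. Here a false discovery rate of 0.01 left 189 higher and 76 lower for PROTAC against DMSO, 900 higher and 837 lower for UNC against DMSO, 337 higher and 74 lower for PROTAC against UNC, and 206 shared by both treatments. Here an absolute log2 fold change of at least 1 left 3 higher and 15 lower for PROTAC against DMSO, 35 higher and 231 lower for UNC against DMSO, 100 higher and 8 lower for PROTAC against UNC, and 10 shared by both treatments. Without a filter the paired covariance was 0.529. Leaving out a library or number in the paired fit gave 91 to 391 higher and 56 to 248 lower for PROTAC against DMSO, 580 to 1432 higher and 617 to 1355 lower for UNC against DMSO, 261 to 494 higher and 45 to 237 lower for PROTAC against UNC, 98 to 439 shared and a covariance of 0.0622 to 0.127.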

Other observations

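The placental and contractile lists, and all tests of explanations below, were chosen after the largest changes had been seen. The p-values of these 2 lists are therefore descriptive only. Hormones and fusion proteins of the placenta fell with UNC in the paired fit: of 23 placental genes 1 rose, 15 fell and 7 were not called (camera adjusted p = 3.00e-09, median log2 fold change -1.29, adjusted p = 0.122 with an estimated correlation). By group alone 2 fell and no member rose (1 at an unadjusted p under 0.05 by edgeR, 1 called by DESeq2 and 0 by limma-voom), with a camera adjusted p = 3.23e-07, and adjusted p = 0.469 with an estimated correlation. Placental lactogens CSH1 (-1.24) and CSH2 (-1.68), which are near-identical and can trade reads, the chorionic gonadotropin subunit CGB3 (-1.81), leptin LEP (-2.63) and the envelope gene ERVV-1 (-0.70) fell, while the protease PAPPA2 (0.45) rose. LEP was at 0.204 CPM or less in each UNC library. Of the 23 placental genes, 6 were higher with PROTAC than with UNC in the paired fit, LEP (3.28) and CSH2 (1.37) among them. By group alone it was 0 by edgeR (6 at an unadjusted p under 0.05), 3 by DESeq2 and 0 by limma-voom. With PROTAC against DMSO 1 rose and 2 fell in the paired fit, 19 of 23 being negative (median -0.26, camera adjusted p = 0.00666, adjusted p = 0.292 with an estimated correlation). By group alone the list was not called (camera adjusted p = 0.0757), and edgeR, DESeq2 and limma-voom called 0 members (1 higher and 2 lower at an unadjusted p under 0.05 by edgeR).

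Genes of the contractile apparatus also fell with UNC in the paired fit. Of 23 listed, 1 rose, 13 fell and 9 were not called (camera adjusted p = 2.11e-05, median log2 fold change -0.26, adjusted p = 0.482 with an estimated correlation), and by group alone 1 rose and 3 fell. Cardiac actin ACTC1 (-1.25), skeletal actin ACTA1 (-1.26), the myosin light chain MYL9 (-0.72) and TAGLN (-1.17) fell, and the intermediate filament gene DES (0.64) rose. Between the compounds 8 were higher and 1 lower with PROTAC in the paired fit. By group alone edgeR called 0 and 0 (9 and 1 at an unadjusted p under 0.05), DESeq2 2 and 1, and limma-voom 0 and 0.

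Trophoblast genes were lower with UNC, with a paired median log2 fold change of -0.52 (camera adjusted p = 6.75e-08, adjusted p = 0.378 with an estimated correlation). Leaving out 1 library gave -0.474 (without DMSO 2) to -0.594, and thinning all libraries to equal total counts gave -0.506, which argues against 1 library and against unequal total counts as the cause. Fewer trophoblast-like cells in the UNC cultures would lower the list's members together: 20 fell, but 3 rose, PEG10 and S100P among them. Whether pluripotent cells also make the members that rose was not tested, so a change in cell share and a change within cells cannot be told apart.

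The covariance of the fold changes of both treatments holds between libraries that share no control. Over 6 pairs of a PROTAC and a UNC fold change from different replicate numbers it was positive in 6, with a mean of 0.0263 (SD 0.00998, 0.0174 to 0.0443), which argues against shared DMSO libraries as the whole cause. Restricted to genes over 2 CPM the mean was 0.0158 (SD 0.00271), so genes of low counts are not the whole cause either. The mean correlation of the 6 pairs over all genes was 0.111, against 0.508 where a DMSO library was shared. Between different numbers it was 0.0852 within PROTAC and 0.242 within UNC. The 6 pairs reuse the same libraries and are not independent, so their SD is not an error of the mean. A shared response to PRC2 loss is consistent with these values and stays a hypothesis, and a shared response to any added compound was not tested.

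Other splits of the libraries were too few for a share under 0.05 in the comparisons with DMSO. For PROTAC against DMSO, 10 of 10 splits gave as many calls by group alone (real 0, highest other 0), and in the paired fit 1 of 4 (real 724, highest other 0). For UNC against DMSO it was 1 of 10 (real 174, highest other 0) and 1 of 4 (real 3265, highest other 0). Of the 108 relabellings within numbers 40 were drawn, and 1, the real one with 542 shared calls, was as large (highest other 232, median 0). This share is under 0.05 among the relabellings drawn, the others were not run, and because all 3 groups were exchanged at once it does not separate a shared effect from the changes with UNC alone.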
